A study of Mus musculus with 128 samples.

How the data were processed

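The series measured polyA RNA in single mouse oocytes at MII and in single embryos of 2, 4 and 8 cells by SMART-Seq amplification and paired-end sequencing with a read length of 150 bp. The labels give 16 replicates for each of the 8 groups of stage and genotype. Per the labels' protocols, wildtype or knockout oocytes were fertilized with Kdm4a-knockout sperm, second polar bodies were checked 6 h later, and both genotypes were sampled together when control embryos reached the stage. The zona pellucida, the glycoprotein coat of the egg, was removed and each oocyte or embryo was put in its own tube of an 8-tube strip, lysed and amplified, and libraries were made with Nextera XT. The labels name the amplification kit as SMART-Seq v4 in the series text and as a stranded SMART-Seq kit in the extraction text, and the strand setting of the counting is not given in the sources used here.

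The deposited values are estimated counts per gene that need not be whole: 30.56% of the non-zero values were not whole numbers, as can arise when a read that maps to several places is split between genes. Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned with STAR 2.5.1a to mm10 and counted with featureCounts 1.5.1. Genes were named after GENCODE release M18 per the deposited file's name. Identifiers and positions printed here come from the GENCODE M21 annotation of mm10; of 26855 genes with a single M21 symbol, 99.926% overlapped the M21 position and 80.067% had the same start and end. Members of multi-copy families can share reads in such counting, and overlapping or antisense genes cannot be told apart without the strand setting.

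From these values, counts were rounded to whole numbers, and libraries with under 100000 counts were left out, which removed 8-cell knockout replicate 4 with 419 counts. The other 127 libraries held 528377 to 4657857 counts (median 2130015). A chi-square comparison of all pairs within groups gave at least 4.75 per gene, so no pair within a group lay within sampling noise. Genotype effects were tested per stage with edgeR 4.0.16 (quasi-likelihood F test with robust dispersion, TMM factors, filterByExpr by group) under R 4.3.3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Interactions of genotype and stage, and stage changes within a genotype, came from a 4-group edgeR fit of each pair of adjacent stages; stage changes also needed an absolute log2 fold change of at least 1. Log2 fold changes are knockout minus wildtype, and CPM values are rounded counts over the library total. Where a gene is given as lower or higher in a number of knockout libraries, these lay below or above the median CPM of the wildtype libraries, and the ranges of the genotypes can overlap. Alternatives used DESeq2 1.42.0, RLE factors, limma 3.58.1 (voom with quality weights), no or a stricter filter (10 CPM in 16 libraries), a log10 depth covariate, the replicate number as a block, all 8 groups in one fit, an absolute log2 fold change of at least 1, and each replicate left out in turn. The replicate number was treated as a name, since the checks of pairing found no shared deviation.

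Gene lists were tested with camera on limma-voom values with a preset correlation of 0.01, Benjamini-Hochberg adjusted over 85 tests of a list at a stage, with at least 5 members measured; camera with an estimated correlation and fry were alternatives. Transcripts that rise or fall at a step were defined in odd-numbered wildtype libraries (edgeR adjusted p under 0.01 and an absolute log2 fold change of at least 2) and tested between even-numbered wildtype (n = 8) and knockout libraries, so that no library both defined and tested a set. The expression filter of these set tests goes by the smaller group. Members near the floor can therefore pass it through the knockout libraries alone, which can raise the median and the camera result of a set. Values of single members come from the genotype fit of each stage, which uses the odd-numbered wildtype libraries as well. Shares of counts, Kdm4a levels and library quality were compared by two-sided permutation tests with 100000 resamples, exact where a group had fewer than 10 values. Overlaps were tested with Fisher's exact test, one-sided for more overlap. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

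Designs, tests, the 25 gene lists, 152 alternatives and the rule for named genes were fixed before the data were examined. The rule names Kdm4a; per genotype comparison the 6 higher and 6 lower genes with the largest log2 fold change among those called, with a mean of at least 20 CPM in the higher group and a symbol that is not a clone or provisional name; per list up to 4 called members with the smallest p at the stage with most calls, or where none is called the 2 with the highest mean; per interaction the 4 genes each way with the smallest p; per wildtype stage change the 4 each way with the largest fold; and per set 4 members with the smallest adjusted p. Some named genes are left out for length, and some items withheld for evaluation are not reported here. The alternatives that leave out MII knockout replicate 15, 2-cell knockout replicate 13 and 8-cell knockout replicate 7, and those that split replicates 1 to 8 from 9 to 16, were chosen after seeing the data; the labels name tube strips but do not say which tubes shared one.

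Each fit was tested on simulated counts with 200 changed genes. Among changed genes that passed the filter, changes of 0.5, 1 and 2 log2 units were recovered at 46.3%, 93.5% and 100% in MII oocytes, 31.7%, 80.0% and 100% in 2-cell embryos, 10.8%, 55.4% and 100% in 4-cell embryos and 0%, 50.8% and 91.9% in 8-cell embryos, with 1.99%, 3.57%, 3.88% and 6.32% of calls false. For the interactions recovery was 10.8%, 41.0% and 86.2% from MII to 2-cell, 0%, 18.8% and 65.1% from 2-cell to 4-cell, and 4.69%, 18.8% and 72.3% from 4-cell to 8-cell, with 2.22%, 3.64% and 8.82% of calls false. A shifted gene set was found at each of the 4 stages, with 0 unshifted sets called by camera. The simulated genes were drawn independently of each other, so this does not test camera where genes vary together. In other splits of the real libraries camera called a median of 1, 2, 3 and 6 gene lists by stage, adjusted within the stage. A change of 0.5 log2 units in 8-cell embryos would mostly be missed, and the parts of depth and of spread between libraries in this were not separated. A count of 0 was read as a level of up to 3 counts of the library total, for counting error only, since amplified reads are not independent molecules.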

Results

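Messenger RNA was sequenced from single mouse MII oocytes, which are mature unfertilized eggs, and from single embryos at the 2-cell, 4-cell and 8-cell stages (1.5, 2.5 and 3.5 days post fertilization), all of the C57BL/6 strain. At each stage 16 libraries were labelled wildtype and 16 were labelled knockout for Kdm4a, a JmjC-domain histone demethylase that acts on methylated H3K9 and H3K36. Wildtype and knockout oocytes were both fertilized with knockout sperm, so the wildtype embryos carried a functional Kdm4a copy from the mother alone and the knockout embryos carried none. The comparisons therefore ask what the maternal Kdm4a copy contributes to the transcripts of the oocyte and of the early embryo. The table held 41300 genes in 128 libraries. Total counts per library ran from 2123598 to 3766643 in wildtype and 2496970 to 4657857 in knockout oocytes, and from 1756614 to 2916460 and from 528377 to 3434766 in 2-cell embryos. They ran from 1691764 to 2563727 and from 1455238 to 2671024 in 4-cell embryos, and from 1534786 to 3089847 in 8-cell wildtype embryos. The 8-cell knockout libraries reached 3919768 counts, but replicate 4 held 419 and was left out, which leaves n = 15 in that group and n = 16 in every other. No pair of libraries of the same group had counts within sampling noise of each other. No label names the mothers, so the p-values measure the spread between oocytes or embryos and not between females.

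Kdm4a (ENSMUSG00000033326.15, chromosome 4, 118136957 to 118180043 on the minus strand in mm10, GENCODE M21 annotation) was lower in the libraries labelled knockout at the MII, 2-cell and 4-cell stages. In MII oocytes its level was 10.9 ± 3.05 CPM (counts scaled to the library total, mean ± SD, n = 16, range 4.60 to 16.2) in wildtype and 1.28 ± 0.904 CPM (0 to 3.76) in knockout. In 2-cell embryos it was 15.1 ± 4.81 CPM (5.09 to 22.6) against 2.65 ± 1.83 CPM (0 to 6.02). At both stages 0 of 16 knockout libraries lay above the wildtype median. The permutation p of 2e-05 (4e-05 after Benjamini-Hochberg adjustment over the 4 stages) is the smallest that 100000 resamples can give. The edgeR log2 fold change was -3.0 (SE 0.24) in MII oocytes and -2.42 (SE 0.30) in 2-cell embryos. In 4-cell embryos the level was 4.59 ± 3.58 CPM against 1.76 ± 1.47 CPM (permutation p = 0.00536, adjusted 0.00715; 3 of 16 knockout libraries above the wildtype median). In 8-cell embryos it was 1.31 ± 1.16 CPM in wildtype and 1.99 ± 2.22 CPM in knockout (permutation p = 0.294), with 6 wildtype and 4 knockout libraries at 0 counts. In 8-cell libraries a count of 0 allows a level of up to 0.971 to 1.96 CPM in wildtype and 0.765 to 1.97 CPM in knockout, counting error only. The labels do not say which exons were deleted, and the counts cover the whole gene.

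**Figure D1:**
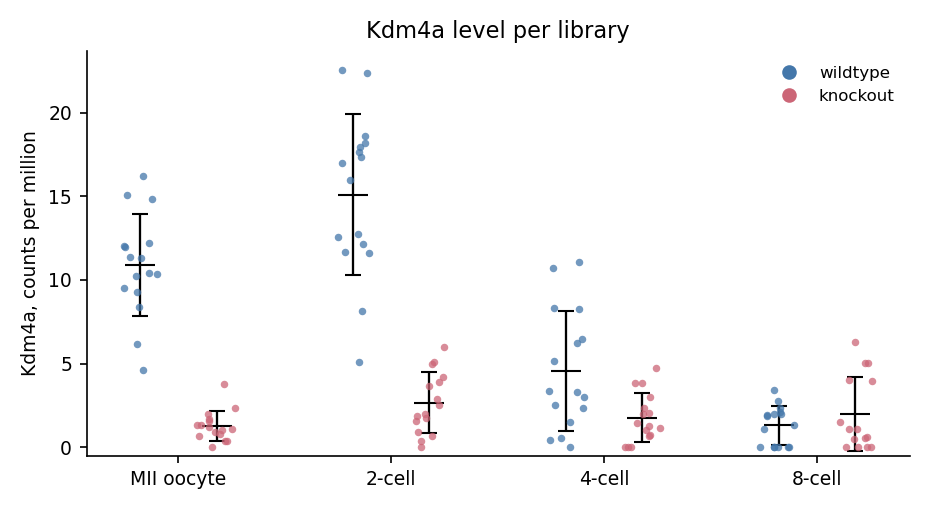
Kdm4a level in CPM (vertical axis) for each library of the 8 stage and genotype groups (horizontal axis), with the mean and SD of each group. Knockout libraries lie between 0 and 3.76 in MII oocytes and between 0 and 6.02 in 2-cell embryos, where the wildtype means are 10.9 and 15.1.

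In MII oocytes, a group of genes was much lower in knockout. Lepr, the leptin receptor, was lower by a log2 fold change of -2.21 (SE 0.25; 29.0 ± 8.33 CPM in wildtype, 6.08 ± 4.53 CPM in knockout), Fgf7, a fibroblast growth factor, by -2.19 (SE 0.27). Serpinb3a, a serpin protease inhibitor, was lower by -1.98 (SE 0.17; 64.0 ± 17.5 to 16.0 ± 5.80 CPM) and Ttc6, a tetratricopeptide repeat protein, by -1.66 (SE 0.14; 86.2 ± 18.7 to 26.8 ± 7.97 CPM), and all of these lay below the wildtype median in 16 of 16 knockout libraries. Later counts of this form use the wildtype median too. Speer4f2, of a spermatid-linked gene family, was lower by -3.53 (SE 0.55), and Nlrc4, an inflammasome sensor, by -1.62 (SE 0.33; 15 of 16 libraries). Among genes that were higher, Tpm4, a tropomyosin, stood at 1.58 (SE 0.29) and Fam32a at 1.46 (SE 0.20), both in 16 of 16 knockout libraries. Pebp1, a Raf kinase inhibitor protein, was at 1.50 (SE 0.27), Calm2, a calmodulin gene, at 1.30 (SE 0.28) and Mis18a, needed to load the centromeric histone CENP-A, at 1.29 (SE 0.39), each in 15 of 16. Adjusted p-values of these genes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment ran from 4.96e-11 for Ttc6 to 0.0272 for Mis18a. Naca, a subunit of the nascent polypeptide-associated complex, had a log2 fold change of 1.62 (SE 0.48), which rested on knockout replicate 15: without that library it was 0.11 (edgeR adjusted p = 0.552).

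In all, 405 genes were higher and 514 lower in knockout oocytes among 7680 tested with edgeR. Among gene lists fixed beforehand, whose number of calls per stage, adjusted within the stage, was also reached by other splits of the same libraries, the spliceosome had 5 of 29 measured members that were lower, 1 higher and 23 not called, the same numbers when adjusted over the list alone. Its median log2 fold change was -0.31 (camera adjusted p = 0.00278, and adjusted p = 0.855 with an estimated correlation). Without knockout replicate 15 the median was -0.17, with 8 members lower and 2 higher (camera adjusted p = 0.0102). Of the mitochondrially encoded genes, 2 of 12 were lower and none higher, again the same when adjusted over the list alone. Over the members the median was -0.30 (camera adjusted p = 0.0181, and adjusted p = 0.908 with an estimated correlation). Without replicate 15, 7 were lower. The median was -0.60 in replicates 1 to 8 and, with knockout replicate 15 included, -0.07 in replicates 9 to 16 (camera adjusted p = 0.940). The called members were mt-Nd6 at -0.44 (SE 0.14) and mt-Nd3 at -0.48 (SE 0.16), subunits of respiratory complex I, each lower in 14 of 16 libraries. The share of counts in mitochondrially encoded genes was 1.37% ± 0.253 in wildtype and 1.23% ± 0.665 in knockout (permutation p = 0.505; adjusted 0.673). It reached 3.58% in one knockout library, and without replicate 15 the knockout mean was 1.07% ± 0.228, below wildtype in a permutation test (adjusted p = 0.0179). Leaving out that replicate, which had the fewest genes detected of its stage, raised the number of calls to 759 higher and 758 lower. Within replicates 1 to 8 edgeR called 289 genes higher and 369 lower, and within replicates 9 to 16, replicate 15 included, it called 53 and 111.

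In 2-cell embryos, among genes of at least 20 CPM with other than clone or provisional names, the largest decreases in knockout included Zfp30, a zinc-finger protein, with a log2 fold change of -3.0 (SE 0.41; 46.1 ± 29.5 CPM to 5.76 ± 4.60 CPM), and Themis, known from T-cell development, at -2.61 (SE 0.29). Cyp2c29, a cytochrome P450, stood at -2.48 (SE 0.31; 70.7 ± 25.6 to 11.9 ± 10.6 CPM) and Lepr at -2.46 (SE 0.22; 67.6 ± 28.2 to 11.95 ± 5.38 CPM). Each of these 4 was below the wildtype median in 16 of 16 knockout embryos, though the ranges of Zfp30 and Cyp2c29 overlapped between genotypes. Fam136a at -2.46 (SE 0.48; 16 of 16) and Hesx1, a homeobox transcription factor, at -2.41 (SE 0.43; 15 of 16) were also lower. Among genes that were higher, Ero1l, an oxidoreductase of the endoplasmic reticulum, differed by 1.61 (SE 0.39), Psma5, a proteasome subunit, by 1.37 (SE 0.27; 99.1 ± 64.0 to 248 ± 97.7 CPM) and Nup93, a nuclear pore protein, by 1.33 (SE 0.31), all in 16 of 16 libraries. Adjusted p-values of these genes in edgeR's quasi-likelihood test ran from 3.56e-10 for Lepr to 0.00444 for Ero1l. In all, 633 genes were higher and 873 lower among 8728 tested, and 32 and 394 with an absolute log2 fold change of at least 1 as well.

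The genes switched on transiently at the 2-cell stage were lower in knockout as a list: 8 of 25 measured members were lower, none higher and 17 not called, with 12 lower when adjusted over the list alone. The median log2 fold change was -0.99 (camera adjusted p = 4e-06, and adjusted p = 0.866 with an estimated correlation). The named members were Tmem92 at -1.68 (SE 0.26; 99.3 ± 70.9 to 29.7 ± 13.4 CPM) and Ubtfl1 at -1.39 (SE 0.22; 120 ± 50.3 to 44.3 ± 22.3 CPM), each lower in 16 of 16 embryos. Tdpoz5 was at -1.58 (SE 0.43; 14 of 16) and Usp17lc at -0.86 (SE 0.25; 13 of 16). Several of these belong to multi-copy families, and 81.9% of the non-zero values of Tmem92 were not whole numbers, so values of single family members are uncertain. Cytosolic ribosomal protein genes were lower in 19 of 43 measured members with none higher and 24 not called (22 lower and 2 higher when adjusted over the list alone). As a list its median was -0.43 (camera adjusted p = 7.5e-05, and adjusted p = 0.908 with an estimated correlation). Rps27 stood at -1.34 (SE 0.32), Rpl6 at -1.14 (SE 0.30), Rpl23 at -1.01 (SE 0.23) and Rpl30 at -0.87 (SE 0.22). Of the spindle and chromosome segregation genes, 9 of 36 were higher, 1 lower and 26 not called (12 higher and 2 lower when adjusted over the list alone). The median over this list was 0.27 (camera adjusted p = 0.00607, and adjusted p = 0.558 with an estimated correlation). They included Ccnb1, the mitotic cyclin B1, at 0.77 (SE 0.13; 4390 ± 1194 to 7267 ± 1108 CPM; 16 of 16 libraries), Ccnb2 at 0.68 (SE 0.14), the checkpoint protein Bub3 at 0.79 (SE 0.13) and, lower, the centromeric histone Cenpa at -0.65 (SE 0.15). Maternal-effect genes were higher in 6 of 33 members and lower in none, the same when adjusted over the list alone, with 27 not called. The list's median was 0.18 (camera adjusted p = 0.0181, and adjusted p = 0.908 with an estimated correlation). In replicates 9 to 16 alone camera called neither the maternal-effect genes (median -0.0005, adjusted p = 0.628) nor the spindle list (0.13, adjusted p = 0.205).

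Mitochondrially encoded genes were lower in 2 of 13 members of the list in knockout 2-cell embryos (7 when adjusted over the list alone), with none higher. Its median was -0.51 (camera adjusted p = 7.08e-04, and adjusted p = 0.908 with an estimated correlation). This moved with the replicate numbers: the list's median was -1.03 in replicates 1 to 8 and 0.11 in replicates 9 to 16. Without knockout replicate 13, 8 members were lower over all genes. The mitochondrial share of counts was 4.06% ± 1.37 in wildtype and 3.06% ± 0.764 in knockout (permutation p = 0.0138, adjusted 0.110). The number of genes detected after thinning to 100000 counts was 8728 ± 411 against 8364 ± 280.0 (permutation p = 0.00624; adjusted 0.0998). Within replicates 1 to 8 edgeR called 587 genes higher and 770 lower, and within replicates 9 to 16 it called 37 and 103. In a fit with a term for genotype by range of replicate numbers, 59 genes differed between the ranges.

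Transcripts that rise from the oocyte to the 2-cell stage, defined in the odd-numbered wildtype libraries alone, made up 7.84% ± 1.65 of counts in the even-numbered wildtype 2-cell embryos (n = 8) and 5.66% ± 0.821 in knockout (n = 16; exact permutation p = 1.14e-04, adjusted 3.42e-04). Of the knockout embryos 0 of 16 lay above the wildtype median. With the defining and testing wildtype libraries exchanged the difference was -1.38 percentage points (exact permutation p = 0.0138, adjusted 0.0308). Of 1108 measured members 70.7% had a negative log2 fold change, with a median of -0.45 (camera p = 2.39e-11; p = 0.0236 with an estimated correlation). Members included Cript at -0.79 (SE 0.10; 750.3 ± 169 to 420 ± 58.3 CPM), Sccpdh at -1.74 (SE 0.26) and Cml2 at -1.15 (SE 0.17), each lower in 16 of 16 embryos. Transcripts that fall over the same step held 3.64% ± 0.583 of counts in wildtype and 4.46% ± 0.996 in knockout (exact permutation p = 0.0325, also after adjustment), with 12 of 16 knockout embryos above the wildtype median. The call was lost when the defining and testing wildtype libraries were exchanged (exact permutation p = 0.0635), as mean log2(CPM + 1) (p = 0.462) and in replicates 9 to 16 (p = 0.885), where the median log2 fold change of the set was -0.0095. In all libraries the median was 0.11 (camera p = 0.0288; p = 0.388 with an estimated correlation). Ube2t, a ubiquitin-conjugating enzyme of the Fanconi anemia pathway, was higher by 1.08 (SE 0.14), Ywhab, a 14-3-3 protein, by 0.93 (SE 0.13) and Ccdc69 by 0.66 (SE 0.10). Sumo2, a small ubiquitin-like modifier, was lower at -1.45 (SE 0.23).

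**Figure D2:**
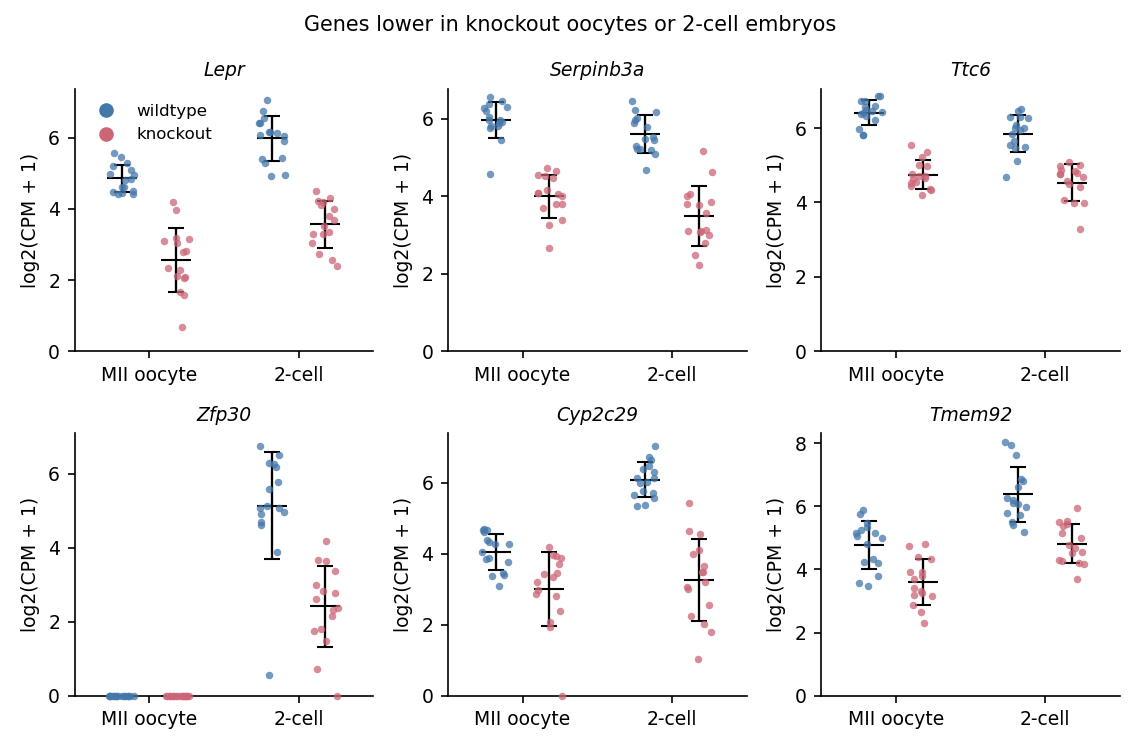
Expression as log2(CPM + 1) (vertical axis) of Lepr, Serpinb3a, Ttc6, Zfp30, Cyp2c29 and Tmem92 in each wildtype and knockout library of MII oocytes and 2-cell embryos, with group means. Lepr is below the wildtype median in 16 of 16 knockout libraries at both stages.

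In 4-cell embryos, transcripts that normally fall after the 2-cell stage were higher in knockout. They made up 3.46% ± 0.394 of counts in the even-numbered wildtype embryos (n = 8) and 4.92% ± 0.590 in knockout (n = 16; exact permutation p = 8.16e-06, adjusted 4.90e-05), with 16 of 16 knockout embryos above the wildtype median. With the defining and testing wildtype libraries exchanged the shares were 4.15% ± 1.21 and 5.14% ± 0.651 (exact permutation p = 0.0154, adjusted 0.0308). All 16 knockout embryos again lay above the wildtype median, but the highest wildtype embryo held 6.65% and the highest knockout embryo 6.49%. Before the exchange the median log2 fold change of 1207 measured members was 0.64 (camera p = 6.13e-14; p = 1.19e-05 with an estimated correlation). Members near the floor can pass the expression filter through the more numerous knockout libraries alone, which can raise this median and the camera result. The median was 0.46 over 1337 members after the exchange. It was 0.47 over 1007 members in the genotype fit, which has 16 libraries of each genotype and includes the defining ones. The shares of counts use every member without this filter. Ccdc6 was higher by 1.63 (SE 0.19; 106 ± 40.2 to 328 ± 132 CPM), Cul1, the cullin of SCF ubiquitin ligases, by 1.34 (SE 0.16; 195 ± 75.5 to 494 ± 112 CPM). Strn, a striatin, was higher by 1.30 (SE 0.16) and Ube2d2a, a ubiquitin-conjugating enzyme, by 0.99 (SE 0.11), and all 4 were higher in 16 of 16 embryos. Transcripts that rise from the 2-cell to the 4-cell stage held 42.0% ± 2.04 of counts in wildtype and 39.7% ± 2.45 in knockout (exact permutation p = 0.0308, adjusted 0.0325), with 4 of 16 knockout embryos above the wildtype median. The call was lost with the wildtype libraries exchanged (a difference of -2.03 points, exact permutation p = 0.111) and in replicates 1 to 8 (-1.15 points, p = 0.513). Their median log2 fold change was -0.19 (camera p = 1.94e-08; p = 0.00166 with an estimated correlation). Sap30bp at -0.99 (SE 0.12), Chchd2 at -0.80 (SE 0.10) and Hif1an, an oxygen-sensing hydroxylase, at -1.58 (SE 0.20) were lower in 16 of 16 knockout embryos.

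In all, 671 genes were higher and 558 lower in 4-cell knockout embryos among 7478 tested with edgeR. Snrpn, an imprinted gene expressed from the paternal copy and coding for the splicing protein SmN, was higher by 2.21 (SE 0.28; 36.9 ± 23.5 to 169.9 ± 49.8 CPM), and Snhg14, the noncoding transcript of the same imprinted region, by 1.98 (SE 0.25). Overlapping genes share reads where counting does not use strand, and the strand setting is not given in the sources used here. Nlrp4c, an oocyte-expressed NLR protein, at 2.35 (SE 0.59), Trim61 at 2.08 (SE 0.28), Arid2, a SWI/SNF chromatin remodelling subunit, at 2.01 (SE 0.31) and Art3 at 2.09 (SE 0.43) were higher. Dnah3, a dynein heavy chain, at -2.25 (SE 0.47), Nupr1, a stress-induced transcriptional regulator, at -2.02 (SE 0.29; 64.2 ± 48.4 to 15.7 ± 5.83 CPM) and Tollip, a Toll-pathway adaptor, at -1.72 (SE 0.27) were lower in 16 of 16 knockout embryos. Art3 was higher in 15 of 16. Adjusted p-values of these genes in edgeR's quasi-likelihood test ran from 1.40e-06 for Snrpn to 0.00554 for Nlrp4c.

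Oocyte-specific transcripts were higher in 7 of 25 measured members in 4-cell knockout embryos, none lower and 18 not called (12 higher when adjusted over the list alone). Over the members the median was 1.08 (camera adjusted p = 2.3e-05, and adjusted p = 0.449 with an estimated correlation). Of the maternal-effect genes 7 of 24 were higher, 1 lower and 16 not called (8 and 2 when adjusted over the list alone; camera adjusted p = 0.415). Among them were Nlrp9c at 1.46 (SE 0.24), Dnmt3l, a cofactor of DNA methyltransferases, at 1.46 (SE 0.38), the Argonaute protein Ago2 at 0.92 (SE 0.23) and the Polycomb subunit Rnf2 at 0.68 (SE 0.19). Ribosome biogenesis genes were lower in 8 of 39 members, higher in 2 and not called in 29, the same when adjusted over the list alone. As a list its median was -0.30 (camera adjusted p = 1.49e-04, and adjusted p = 0.558 with an estimated correlation). Ebna1bp2 at -0.61 (SE 0.12; 635 ± 120 to 418 ± 106 CPM), Nifk at -0.45 (SE 0.09) and Pa2g4 at -0.41 (SE 0.10) were each lower in 16 of 16 embryos, and Wdr12 was higher at 0.63 (SE 0.13). Cytosolic ribosomal protein genes were lower in 4 of 57 and higher in none (2 lower when adjusted over the list alone). The median over this list was -0.23 (camera adjusted p = 2.3e-05, and adjusted p = 0.908 with an estimated correlation). Spliceosome genes were lower in 6 of 37 and higher in 1 (7 and 1 when adjusted over the list alone). The list's median was -0.22 (camera adjusted p = 0.00296, and adjusted p = 0.449 with an estimated correlation). Of the genes that neighbour Kdm4a on chromosome 4, 4 of 9 were lower and none higher, the same when adjusted over the list alone. Its median was -0.40 (camera adjusted p = 0.0326, and adjusted p = 0.449 with an estimated correlation). They include Ebna1bp2, the mitotic activator Cdc20 at -0.59 (SE 0.19) and Dph2 at -1.02 (SE 0.34). In replicates 1 to 8 alone camera called neither the neighbours (adjusted p = 0.216) nor the spliceosome (adjusted p = 0.0662), and the medians were 0.58 for the oocyte-specific, -0.17 for the ribosome biogenesis and -0.11 for the ribosomal protein genes. Within replicates 1 to 8 edgeR called 76 genes higher and 64 lower, and within replicates 9 to 16 it called 258 and 154.

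**Figure D3:**
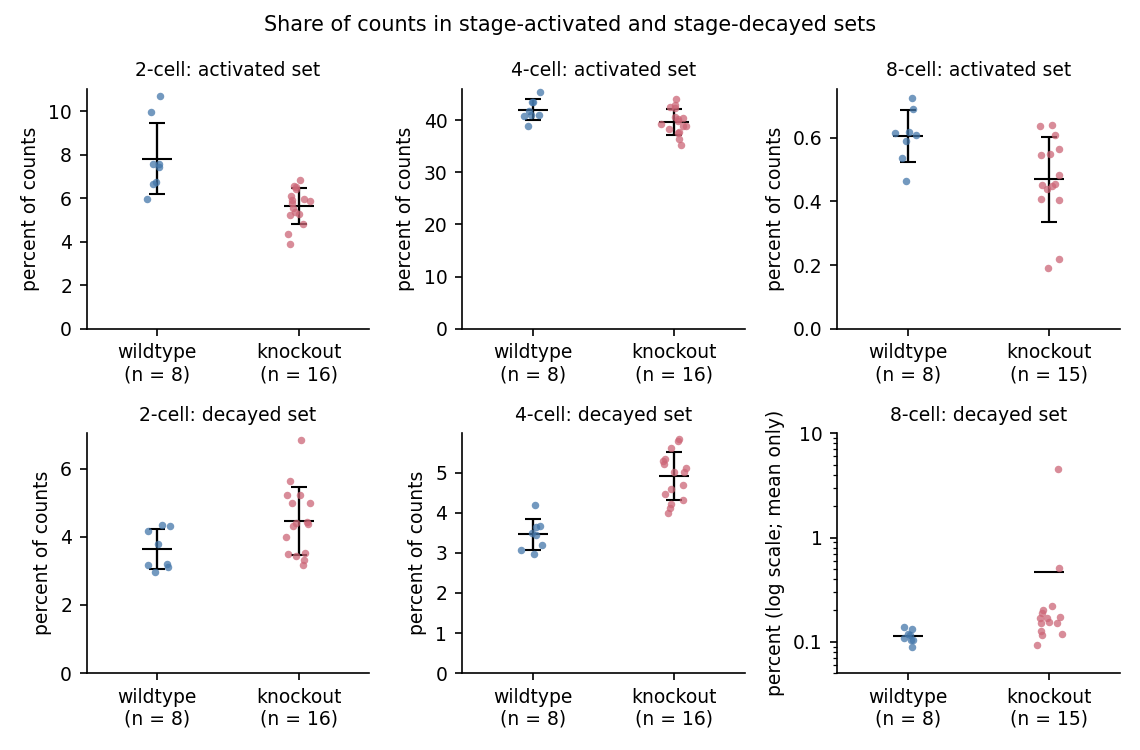
Percent of counts (vertical axis) in transcripts that rise or fall at each step in wildtype, for the even-numbered wildtype libraries and all knockout libraries of the 2-cell, 4-cell and 8-cell stages, with mean and SD; the panel of falling transcripts in 8-cell embryos has a log axis and shows the mean only. At the 4-cell stage the falling transcripts hold 3.46% of counts in wildtype and 4.92% in knockout.

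In 8-cell embryos, Dynap, a dynactin-associated membrane protein, was lower in knockout by a log2 fold change of -2.26 (SE 0.44; 297 ± 125 CPM in wildtype, n = 16, and 62.5 ± 51.2 CPM in knockout, n = 15). Ccdc39, a protein of motile cilia, was lower by -2.21 (SE 0.41), both in 15 of 15 knockout embryos. Prl3b1, a placental lactogen, at -1.69 (SE 0.46), Dcc, a netrin receptor, at -1.50 (SE 0.45), Saxo1 at -1.45 (SE 0.39) and Prep, prolyl endopeptidase, at -1.42 (SE 0.31) were lower as well, in 14 or 15 of 15 embryos. Genes of the p53 and DNA damage response were higher as a list: 5 of 15 measured members were higher, none lower and 10 not called (8 higher when adjusted over the list alone). Over the members the median was 0.69 (camera adjusted p = 0.00163, and adjusted p = 0.449 with an estimated correlation). In replicates 1 to 8 alone, which include the knockout replicate 7 described below, it was 0.42 (camera adjusted p = 0.0508). The mitochondrial share of counts was 6.26% ± 1.25 in wildtype and 8.03% ± 3.66 in knockout (12 of 15 above the wildtype median; permutation p = 0.0628, adjusted 0.335). In replicates 9 to 16, where the p53 list had a median of 0.94, 8 of 8 knockout embryos had a mitochondrial share above the wildtype median (exact permutation p = 0.0311, adjusted 0.166). The mitochondrially encoded genes had a median of 0.31 in all libraries (camera adjusted p = 0.0532) and 0.41 in those replicates (camera adjusted p = 7.58e-04). Trp53inp1, a p53-induced stress protein, was higher by 1.78 (SE 0.34; 42.9 ± 15.6 to 126 ± 84.9 CPM; 13 of 15 embryos). Mdm2, the p53 ubiquitin ligase, was higher by 1.43 (SE 0.29; 49.9 ± 21.1 to 133 ± 87.8 CPM; 13 of 15) and Plk2, a polo-like kinase, by 1.98 (SE 0.54; 12 of 15). Adjusted p-values of the genes in these sentences in edgeR's quasi-likelihood test ran from 0.00174 for Ccdc39 to 0.0255 for Dcc. In wildtype embryos Mdm2, Trp53inp1 and Plk2 were on average higher at the 4-cell than at the 8-cell stage. Mdm2 ran from 42.8 to 355 CPM against 6.95 to 96.7. Trp53inp1 ran from 20.1 to 203 against 5.99 to 63.8, and Plk2 from 7.68 to 104.5 against 1.30 to 54.05. Their increase in knockout can thus not be told apart from a delay in development, which was not tested at this stage.

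One library stood apart. Knockout replicate 7 had a Spearman correlation across genes of 0.183 with the mean of its own group, against 0.678 with knockout MII oocytes and 0.680 with knockout 2-cell embryos. It had 9638 genes detected where the other 8-cell libraries had at least 12192, 18.9% mitochondrial counts where the others had at most 10.2%, and 0 counts of Kdm4a in a total of 2078119. With it, 617 genes were higher and 218 lower among 7219 tested with edgeR. Among called genes of at least 20 CPM with other than clone or provisional names, the largest increases included oocyte transcripts. These were Btg4, an adaptor for maternal mRNA clearance, at 8.05 (SE 1.59), Oog1 at 6.71 (SE 1.25), Zbed3, of the subcortical maternal complex, at 6.70 (SE 1.44), and Obox5, an oocyte homeobox gene, at 6.21 (SE 1.32). Without it, 507 genes were higher and 396 lower. Btg4 was then at 0.47 (edgeR adjusted p = 0.536), Zbed3 at 0.03 (0.981) and Obox5 at 0.42 (0.635), while Oog1 remained higher at 0.91 (0.0192). Of the oocyte-specific transcripts 9 of 14 were higher with the library and 3 of 14 higher and 1 lower without it (9 higher and 1 lower when adjusted over the list alone with it; camera adjusted p = 0.0532 and 0.261). Oosp1, an oocyte-secreted protein, went from 4.46 (SE 0.89) to 1.93 (edgeR adjusted p = 0.00771) and Fbxw24 from 3.72 (SE 0.74) to 1.47 (0.00561). Each of the lower genes named above kept an edgeR adjusted p of at most 0.0199 without replicate 7. Of the p53 response 8 of 15 members were then higher, with a median of 1.11 (camera adjusted p = 3.15e-04). Trp53inp1 was at 1.27, Mdm2 at 1.39 and Plk2 at 2.09, but Rrm2b, a p53-induced ribonucleotide reductase subunit, went from 2.86 to 0.46 (edgeR adjusted p = 0.257). Within replicates 1 to 8 (7 knockout embryos, replicate 7 among them) edgeR called 1 gene, higher in knockout, and within replicates 9 to 16 it called 77 higher and 35 lower. No fit of replicates 1 to 8 without replicate 7 was run, so the low count there does not show that the other embryos lack a difference.

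Camera also placed 4 large lists lower in 8-cell knockout embryos, although edgeR called at most 1 member of each. Cytosolic ribosomal protein genes had 0 of 57 members called by edgeR over all genes and 0 adjusted over the list alone (1 lower at an unadjusted p under 0.05; 0 called by DESeq2 and 10 lower by limma-voom). As a list its median was -0.69 (camera adjusted p = 7.9e-05, and adjusted p = 0.908 with an estimated correlation). Without replicate 7 the median was -0.22 and 9 members were lower (camera adjusted p = 3e-06). Ribosome biogenesis (0 of 38 called by edgeR, 0 adjusted over the list alone, 2 lower at an unadjusted p under 0.05, 1 lower by DESeq2 and 3 by limma-voom; median -0.48; camera adjusted p = 0.0128), nuclear oxidative phosphorylation genes (1 of 51 lower, 0 adjusted over the list alone; median -0.44; 0.00671) and the spliceosome (1 of 37 lower, 1 adjusted over the list alone; median -0.43; 0.0165) each had an adjusted p = 0.908 with an estimated correlation. These last calls were lost without replicate 7, with medians of -0.16, -0.12 and -0.17 and camera adjusted p-values of 0.0589, 0.0817 and 0.125. In replicates 9 to 16 alone the last 2 were not called either (camera adjusted p = 0.125 and 0.0625).

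Transcripts that rise from the 4-cell to the 8-cell stage held 0.607% ± 0.0820 of counts in the even-numbered wildtype embryos (n = 8) and 0.470% ± 0.133 in knockout (n = 15; exact permutation p = 0.00861, adjusted 0.0129; 2 of 15 above the wildtype median), with a median log2 fold change of -0.50 over 95 members (camera p = 7.32e-06; p = 0.246 with an estimated correlation). Without replicate 7 the median was -0.30 (camera p = 5.57e-05). The call of the share was lost with the wildtype libraries exchanged (exact permutation p = 0.139), with a set threshold of 1 (p = 0.0765) and in replicates 9 to 16 (p = 0.198). They include Dynap, Ccdc39, Cmtm7 at -1.27 (SE 0.28) and Cln8 at -1.24 (SE 0.29), each lower in 15 of 15 embryos. Transcripts that fall over this step held 0.114% ± 0.0160 in wildtype and 0.471% ± 1.13 in knockout (exact permutation p = 0.00173, adjusted 0.00346; 14 of 15 above the wildtype median), and 0.181% ± 0.0994 without replicate 7 (exact permutation p = 0.00265; 13 of 14 above). In replicates 1 to 8, which include replicate 7, the call was lost (exact permutation p = 0.0545). Their median was 0.48 over 71 members (camera p = 2.30e-05; p = 0.0499 with an estimated correlation, and 0.145 without replicate 7). Jak2, a cytokine receptor kinase, stood at 5.14 (SE 0.93) with replicate 7 and 1.68 without it, Unc13c at 5.01 (SE 0.96) and 1.60, Nlrp9c at 5.52 (SE 1.04) and 1.18, and Csnk1g3, a casein kinase, at 1.54 (SE 0.31) and 1.33. All of these remained past the edgeR threshold without it (adjusted p at most 0.00533).

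**Figure D4:**
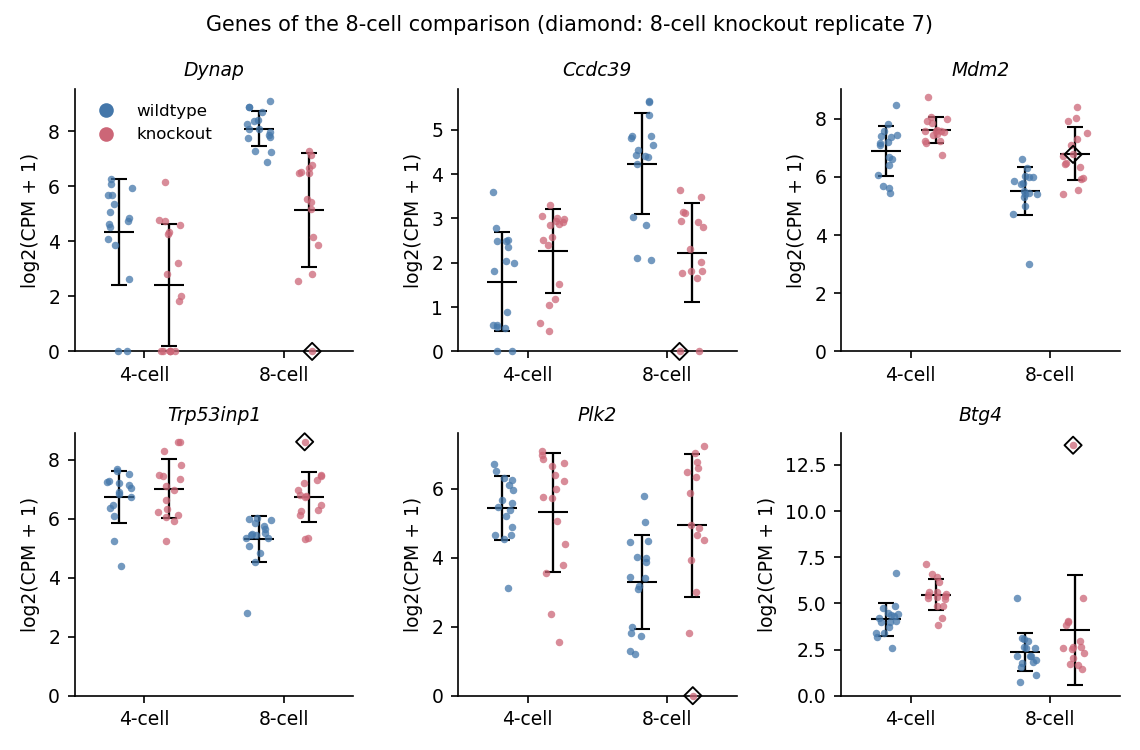
Expression as log2(CPM + 1) (vertical axis) of Dynap, Ccdc39, Mdm2, Trp53inp1, Plk2 and Btg4 in each wildtype and knockout library of 4-cell and 8-cell embryos, with group means; the diamond marks 8-cell knockout replicate 7. Dynap and Ccdc39 are below the wildtype median in 15 of 15 knockout 8-cell embryos, and the large Btg4 mean in knockout comes from the marked library.

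**Figure D5:**
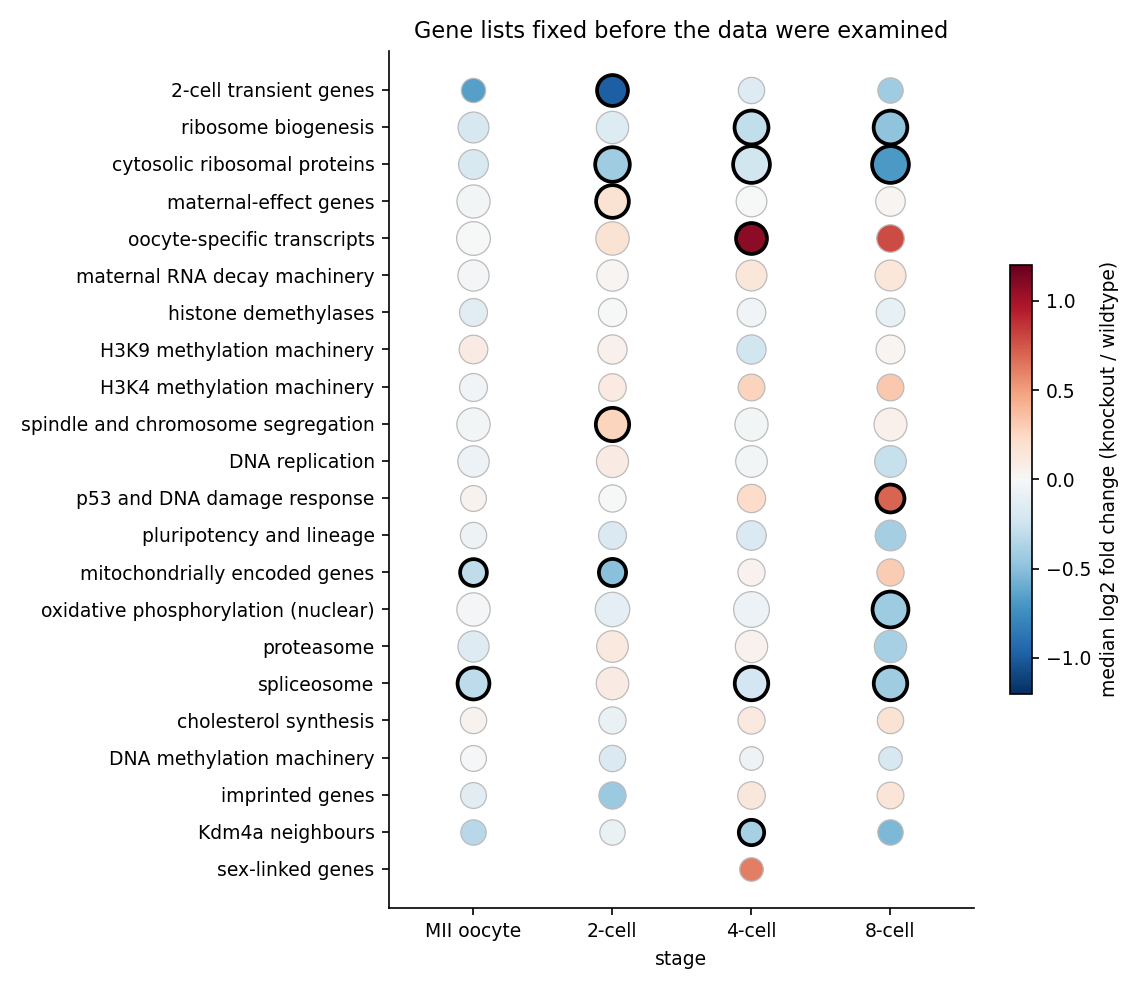
Gene lists (vertical axis) by stage (horizontal axis); colour is the median log2 fold change of knockout minus wildtype, dot size the number of members measured, and a black outline marks lists past the camera threshold with the preset correlation. The 2-cell transient genes at the 2-cell stage have a median of -0.99 and the p53 response at the 8-cell stage one of 0.69.

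Stage changes were tested within each genotype. From the oocyte to the 2-cell stage, edgeR called 3267 genes higher and 1968 lower in wildtype (adjusted p under the threshold and an absolute log2 fold change of at least 1, among 10240 tested). In knockout it called 3134 and 1907, and 4447 were called in the same direction in both. Ubtfl1 at 10.52 (SE 0.39) and Zfp352 at 11.30 (SE 0.47) rose and Plat, tissue plasminogen activator, at -6.82 (SE 0.32) and Bub1b, a spindle checkpoint kinase, at -6.56 (SE 0.28) fell in wildtype. In knockout the values were 9.68, 9.95, -6.86 and -6.32. From the 2-cell to the 4-cell stage 3283 genes rose and 4725 fell in wildtype among 10766 tested, 3515 and 4562 in knockout, and 7266 in the same direction in both. Bhmt, betaine-homocysteine methyltransferase, rose by 7.62 (SE 0.42) in wildtype and 6.77 in knockout, and Ifit1bl2 fell by 11.04 (SE 0.39) and 10.69. From the 4-cell to the 8-cell stage 1816 genes were called in wildtype and 1056 in knockout among 8822, and 560 in the same direction in both. Perp, a desmosomal p53 target, rose by 5.69 (SE 0.72) in wildtype and 4.32 in knockout, and Dab2, an endocytic adaptor of extraembryonic cells, by 5.60 (SE 0.58) and 4.70. These fold changes of genes near 0 at one stage depend on the fit's prior count and are no bounds. Other scalings shifted the median of all genes by 0.119 (RLE) and 0.121 (DESeq2) from MII to 2-cell wildtype, by -0.277 and -0.282 from 2-cell to 4-cell wildtype and by -0.345 and -0.350 for that step in knockout, so a fold change across stages holds relative to those shifts.

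The change between stages differed by genotype, in an interaction test, for 198 genes higher and 211 lower in knockout from the oocyte to the 2-cell stage. Rpl17, a ribosomal protein gene, rose by 1.12 in wildtype and 2.56 in knockout (difference 1.45, SE 0.18). Ccdc69 fell by 2.95 and 2.11 (difference 0.84, SE 0.12), and G6pdx, the first enzyme of the pentose phosphate pathway, rose by 3.21 and 4.39 (difference 1.18, SE 0.19). Fam32a rose by 0.86 in wildtype and fell by 1.01 in knockout (difference -1.87, SE 0.30), and Tpm4 was at 0.35 in wildtype and fell by 2.30 in knockout (difference -2.65, SE 0.44). From the 2-cell to the 4-cell stage 1231 genes were higher and 434 lower in the interaction. Naa30, an N-terminal acetyltransferase, fell by 4.12 in wildtype and 2.37 in knockout (difference 1.75, SE 0.23), and Hmgb1, an abundant chromatin protein, rose by 2.36 and 3.45 (difference 1.09, SE 0.14). Ube2d2a fell by 2.81 and 1.68 (difference 1.13, SE 0.15), and Nckap1, of the WAVE complex, fell by 0.73 and rose by 0.58 (difference 1.31, SE 0.18). Fubp1, a regulator of Myc, rose by 2.48 and 0.66 (difference -1.82, SE 0.27), and Eri1, an exoribonuclease, by 2.39 and 0.79 (difference -1.60, SE 0.25). From the 4-cell to the 8-cell stage 188 genes were higher and 53 lower, and 85 and 81 without 8-cell knockout replicate 7. Snrpn rose by 2.51 in wildtype and was at 0.36 in knockout (difference -2.15, SE 0.33), and Ube2e3 rose by 1.75 and was at 0.05 (difference -1.70, SE 0.26). The higher differences with the smallest p, Tcl1b4 at 8.47 (SE 1.51), Zbed3 at 6.82 (SE 1.32), Obox2 at 6.69 (SE 1.30) and Obox1 at 6.37 (SE 1.27), were lost without replicate 7 (Tcl1b4 1.98, Zbed3 0.45, Obox2 0.71). Adjusted p-values of the interactions named, in edgeR's quasi-likelihood test, ran from 2.75e-07 for Rpl17 from MII to 2-cell to 0.00355 for Obox1. The 2-cell and 4-cell libraries enter more than one of these tests.

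The genotype effects at different stages share no library, so their overlap can be counted. Fisher's test takes genes as independent and equally likely to be called. As genes vary together and differ in level, its p-values can be too small and the counts given by independent lists too low. Between MII oocytes and 2-cell embryos 86 genes were higher at both stages and 131 lower at both, where independent lists would give 32.7 and 34.2 (Fisher's exact p = 6.18e-18 and 2.17e-46). A further 28 went in opposite directions, and the Pearson correlation of log2 fold changes across 6983 genes, which are not independent replicates, was 0.37. Without the libraries that stood apart 154 were higher at both, 167 lower at both and 57 opposite. Lepr, Serpinb3a, Ttc6 and Tmem92 were among the genes lower at both. Between 4-cell and 8-cell embryos 207 were higher at both and 66 lower at both, where 55.9 and 15.1 would be given by independent lists (Fisher's exact p = 1.53e-74 and 9.25e-27). Another 3 went in opposite directions and the correlation was 0.458. Without 8-cell knockout replicate 7 the counts were 162 and 128. Jak2 and Nlrp9c were higher at both. Between 2-cell and 4-cell embryos 48 were higher at both (46.1 given by independent lists; Fisher's exact p = 0.402) and 64 lower at both (40.9; Fisher's exact p = 1.31e-04), with 69 in opposite directions. For oocytes and 8-cell embryos 39 genes went the same way, with 39.4 given by independent lists. Without MII knockout replicate 15 and 8-cell knockout replicate 7, 79 did, with 60.5 given by independent lists (Fisher's exact p = 0.0165 for the 56 higher at both and 0.129 for the 23 lower at both). Between oocytes and 4-cell embryos 40 were higher at both (33.2 given by independent lists; Fisher's exact p = 0.118) and 31 lower at both (18.3; Fisher's exact p = 0.0023), with 0 of the latter at an absolute log2 fold change of at least 1. Without MII knockout replicate 15 these were 68 (60.4; Fisher's exact p = 0.154) and 43 (29.8; Fisher's exact p = 0.00776). Between 2-cell and 8-cell embryos 57 were higher at both (44.0; Fisher's exact p = 0.022) and 18 lower at both (13.2; Fisher's exact p = 0.103), and without the libraries that stood apart 48 (38.4; Fisher's exact p = 0.0581) and 51 (29.7; Fisher's exact p = 5.87e-05).

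The spread of single libraries, 1 minus the mean Spearman correlation of a library with the others of its group after thinning to 100000 counts, is given as values only. Each library enters the values of all others of its group, so they are not independent, and the planned permutation test of them is not reported. In 8-cell embryos the spread was 0.216 ± 0.00387 in wildtype and 0.305 ± 0.126 in knockout, and 0.235 ± 0.0175 in knockout without replicate 7. In 2-cell embryos it was 0.267 ± 0.0117 in wildtype and 0.253 ± 0.00770 in knockout, and in 4-cell embryos 0.246 ± 0.0165 and 0.243 ± 0.0103. In MII oocytes it was 0.195 ± 0.00465 in wildtype and 0.212 ± 0.0367 in knockout, and 0.192 ± 0.00335 in knockout without replicate 15.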

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

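Among the tests below, those of exchanged libraries, of linkage to Kdm4a, of clustering of genes and of developmental delay were chosen only after the result was seen; the others were written down before.

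The difference between genotypes was itself different between adjacent stages for 3 sets of genes: the interaction test called 409 genes from MII oocytes to 2-cell embryos, 1665 from 2-cell to 4-cell embryos and 241 from 4-cell to 8-cell embryos. Of 100 splits of the same libraries, the real one included, 1 gave as many genes in the first step (highest other 1) and 1 in the second (highest other 155), which argues against a chance split of single oocytes and embryos there. Such splits do not exclude differences between females or collections, which the labels do not name. In the last step 3 of 100 did (real 241, highest other 260, median of the others 73), a share under 0.05. As other splits reached counts this large, chance is made less likely there but is not excluded. Without 8-cell knockout replicate 7 the test called 166 genes, 101 of them among the 241, and no other splits were run there, so chance is not excluded for that count.

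The 1st pattern is 8-cell knockout replicate 7, whose profile is closest to oocytes and 2-cell embryos. The tables argue against an exchange with another library of those stages, since 0 of 64 libraries labelled MII or 2-cell were closest to an 8-cell group, and against oocyte RNA mixed into an 8-cell embryo: over 846 genes high in 8-cell embryos and low in oocytes, its median level was 0.0% of that in the other 8-cell knockout libraries (quartiles 0.0 and 1.69%; MII knockout oocytes 1.42%). An egg or embryo that did not activate its genome may account for it, but cannot be told apart from one that activated it in part: its share of counts in 2-cell activated transcripts was 2.17%, above the highest knockout oocyte (1.91%) and below the lowest knockout 2-cell embryo (3.89%), where other 8-cell knockout embryos held 15.2 to 17.8%. Its share of 4-cell activated transcripts, 1.30%, lies below the 1.98 to 5.05% of knockout oocytes. A single wrong label, and an effect of the missing maternal Kdm4a on that embryo, stay open and were not tested.

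The 2nd pattern is a group of 36 genes besides Kdm4a lower by at least 1 log2 unit in knockout at both the MII and the 2-cell stage, with 0 higher by as much at both; 11 of them, all 11 tested genes of that interval, lie on the X chromosome between 25917944 and 35348739 (mm10), with median log2 fold changes of -2.88 and -2.38, and were singled out after their values were seen, since 25 of the 36 have clone names. DNA carried along next to the deleted gene is argued against as the cause of the group as a whole, since 5.56% of members (2 genes, Lepr among them) lie within 20 Mb of Kdm4a. For those 2 genes it stays open, the share given by random genes was not computed, and DNA farther from Kdm4a was not tested. Reads shared between near-identical copies may add to the X-linked part: a median of 98.2% of its non-zero values were not whole (lowest member 86.6%), against 19.5% in genes of matched expression and 43.2% in the other members, so these 11 may be few independent signals. Genes of 1 neighbourhood lowered together stay open too: 12 members have another within 500 kb, but most are the X group that prompted the test, and the 2 among the 25 others are no more than the 95th percentile, 2, of 1000 random sets. This count depends on the distance chosen. RP23-473B17.1, RP24-553G19.2 and RP24-230H12.2 on chromosome 14 start at 41348609, 41924949 and 42463881, slightly farther apart than that. Of their non-zero values 92.8 to 93.5% were not whole, so shared reads may not be confined to the X group. A role of maternal Kdm4a in their expression is a hypothesis that these data leave untested.

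The last pattern is the excess of falling transcripts in 4-cell knockout embryos. A difference in depth is argued against, as the set's median log2 fold change over 1007 members was 0.45 with log10 depth as a covariate (0.4463) and 0.47 without it. Both values come from the fit of all 4-cell libraries, the odd-numbered wildtype ones that defined the set included. A few unusual embryos are argued against as well, since 16 of 16 knockout embryos lay above the median of the even-numbered wildtype embryos. Knockout embryos that were behind in development when sampled by the progress of controls may account for it: the fractions of the way back to the 2-cell profile, 2.78% (SE 0.361) from falling and 6.21% (SE 2.26) from rising transcripts, differed by -3.43 percentage points (SE 2.00, 2000 bootstrap draws), within 2 standard errors. The fraction from rising transcripts is imprecise, and their share was not called with the wildtype libraries exchanged. The comparison could thus hardly have gone against a delay and does not decide the question. A direct effect of the missing maternal Kdm4a on decay or activation is the biological alternative and was not tested.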

How the results depend on the processing

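The alternatives that leave out 3 libraries or use 1 group of replicate numbers were chosen after seeing the data; the others were planned. Of 224 alternative counts of calls 190 stayed within 1.5 times, and of 5281 values of single named genes under alternatives 4860 kept direction and side of the threshold, 409 lost the call, 6 gained one and 6 turned. A larger fold threshold gives fewer genes by construction, and ranges of replicate numbers hold fewer libraries, though leaving out single libraries raised some counts. With log10 depth as a covariate the genotype effects called 857, 1591, 1242 and 847 genes by stage. Depth limits what a count of 0 excludes. For the other changed counts the cause was not tested.

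With an absolute log2 fold change of at least 1, calls were 141, 426 and 454 in MII oocytes, 2-cell and 4-cell embryos, 205 in the first interaction, and genes in the same direction at 2 stages 37 for MII and 2-cell (Kdm4a among them), 2 for MII and 4-cell, 1 for MII and 8-cell, 8 for 2-cell and 4-cell, 4 for 2-cell and 8-cell and 120 for 4-cell and 8-cell, where independent lists give 1.51, 1.52, 2.55, 3.69, 2.21 and 19. With all 8 groups in one fit they were 247, 890, 2080 and 3383 by stage. With replicates 9 to 16 they were 164, 140, 412 and 112, and with replicates 1 to 8 140 in 4-cell and 1 in 8-cell embryos, where knockout replicate 7 is included. Without the low-count filter, which tests more genes, they were 2670 in 4-cell and 2895 in 8-cell embryos, 221 and 1030 in the first and last interaction, and 14100 and 13545, 16904 and 16420, and 4319 and 2869 in the stage changes of wildtype and knockout. In MII oocytes limma-voom gave 1579, and leaving out the 3 libraries gave 1517 there and 722 in the first interaction; leaving out 1 replicate number gave 694 to 1484, the highest without replicate 15. DESeq2 gave 658 in the first interaction and RLE factors 484 in the last.

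The share of calls that were higher moved from 42.03 to 22.7% in 2-cell embryos with all groups in one fit, to 7.51% (32 higher and 394 lower) with an absolute log2 fold change of at least 1 and to 26.43% in replicates 9 to 16. In replicates 9 to 16 it moved from 44.07 to 32.32% in MII oocytes. At the larger fold it moved from 54.6 to 66.08% in 4-cell embryos, from 73.89 to 85.05% in 8-cell embryos and from 48.41 to 26.34% in the first interaction. In 8-cell embryos it moved from 73.89% to 54.21% in DESeq2, 48.85% in limma-voom and 56.15% without knockout replicate 7. Under the same 3 alternatives it moved from 78.01% to 60.93%, 37.44% and 51.2% in the last interaction, and in the last knockout stage change from 67.61% to 55.26%, 53.07% and 49.18%. Without the low-count filter it moved from 62.41 to 79.31% and from 62.17 to 79.41% in the first stage change of wildtype and knockout.

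With a replicate block the 8-cell calls were 115 (64 higher and 51 lower, a median shift of -0.10 over all genes) and the last interaction 34, of which 32.35% were higher, and no other count of calls moved as far. The numbers give no sign of pairing: deviations of same-numbered libraries correlated at -0.287 to 0.183, and 3, 1, 1 and 2 knockout libraries by stage correlated best with their own number.

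Differences in set shares lost the call as follows (percentage points, exact permutation p). Exchanging the wildtype libraries that define and test gave 0.952 for the falling set in 2-cell embryos (p = 0.0635), -2.03 (p = 0.111) for the rising set in 4-cell and -0.118 (p = 0.139) in 8-cell embryos. The falling set in 2-cell embryos gave 0.0554 as mean log2(CPM + 1) (p = 0.462) and 0.0704 in replicates 9 to 16 (p = 0.885), where its median log2 fold change turned to -0.0095. The rising set gave -1.15 in 4-cell embryos in replicates 1 to 8 (p = 0.513), and in 8-cell embryos -1.10 with a set threshold of 1 (p = 0.0765) and -0.0939 in replicates 9 to 16 (p = 0.198). The falling set in 8-cell embryos gave 0.663 in replicates 1 to 8, knockout replicate 7 included (p = 0.0545).

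Of 17 list calls, 0 held in camera with an estimated correlation and 7 in fry, which asks another question and made 8 calls, DNA replication in MII oocytes being the other. The mitochondrial list in 2-cell embryos turned to 0.11 in replicates 9 to 16. Quality differences passed the threshold for the mitochondrial share in MII oocytes without the 3 libraries (-0.303 points, adjusted p = 0.0179) and in replicates 1 to 8 (-0.406), for genes after thinning in 2-cell embryos (-400.9 and -540.2) and for the mitochondrial share there (-1.07 and -2.33). The difference in spread in MII oocytes, given as a value only, turned to -0.00221 without the 3 libraries and -0.00440 in replicates 1 to 8, and in 2-cell embryos it was -0.00927 in replicates 9 to 16. Single genes that turned were Naca in replicates 1 to 8 (-0.028), Zbed3 in 8-cell embryos without replicate 7 of either genotype (-0.0082, against up to 7.68 with another replicate, number 1, left out), Ncoa6 there in limma-voom (-0.11), and in the last interaction in limma-voom Zbed3 (-0.074), Obox2 (-0.068) and Obox1 (-0.19). Leaving out replicate 7 removes the library that carries the oocyte transcripts; for the others the cause was not tested.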

Other observations

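The tests without named libraries and within ranges of replicate numbers were chosen only after the result was seen; all other tests below were planned.

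In 2-cell embryos 4 of 16 histone demethylases besides Kdm4a were lower in knockout, 1 was higher and 11 were not called (4 lower and 2 higher when adjusted over the list alone; camera adjusted p = 0.768). Kdm4c, a demethylase of the same family as Kdm4a, stood at -1.52 (SE 0.35; lower in 15 of 16 embryos), Kdm3a at -1.13 (SE 0.28; 14 of 16), Kdm5b at -0.94 (SE 0.25; 16 of 16) and Phf8 at 0.57 (SE 0.13; higher in 15 of 16). At the 2-cell stage edgeR called 4 of 19 genes of the H3K9 methylation machinery higher and 1 lower. DESeq2 called 4 higher and 3 lower there and limma-voom 3 and 3, so no balance was clear. In 4-cell embryos 5 of 19 were lower and 1 higher in edgeR, also when adjusted over the list alone (camera adjusted p = 0.326). DESeq2 gave 5 lower and 1 higher at that stage and limma-voom 5 and 2. The methyltransferase Suv39h2 was at 1.01 (SE 0.29; 14 of 16), and Atf7ip at -1.04 (SE 0.30; 13 of 16), Mphosph8 at -0.69 (SE 0.20; 15 of 16) and Zfp809 at -1.02 (SE 0.32; 13 of 16) were lower. In 8-cell embryos 4 of 12 genes of the H3K4 methylation machinery were higher and 0 lower (6 and 1 when adjusted over the list alone; camera adjusted p = 0.0678). Kmt2e was at 1.19 (SE 0.29; 15 of 15), and the other 3 calls were lost without knockout replicate 7. Of the DNA methylation machinery, Dnmt3l was the 1 of 6 members called in 4-cell embryos, also when adjusted over the list alone (camera adjusted p = 0.956).

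Machinery of RNA decay, protein breakdown and growth also held single calls in 2-cell embryos. Of the maternal RNA decay machinery 5 of 27 were lower and 3 higher, also when adjusted over the list alone (camera adjusted p = 0.911). Later the balance was the other way, with 6 of 25 higher and 1 lower in 4-cell embryos and 7 of 25 higher and 0 lower in 8-cell embryos, replicate 7 included. In 2-cell embryos the deadenylase subunits Cnot2 at -0.69 (SE 0.13) and Cnot10 at -1.22 (SE 0.30) and the uridylyltransferase Zcchc11 at -1.30 (SE 0.38) were lower in 16 of 16 embryos. Of the proteasome at that stage 5 of 28 were higher and 1 lower (6 and 1 when adjusted over the list alone; camera adjusted p = 0.122), with Psma2 at 1.05 (SE 0.23; 15 of 16) and Psmc3 at -0.90 (SE 0.26; 15 of 16). Of nuclear oxidative phosphorylation genes 4 of 42 were higher and 4 lower (6 and 5 when adjusted over the list alone; camera adjusted p = 0.885), and Atp5b stood at 0.60 (SE 0.13; 16 of 16). Of cholesterol synthesis genes 1 of 13 was higher, Nsdhl at 0.75 (SE 0.22), and 1 lower, Fdps at -0.87 (SE 0.26), also when adjusted over the list alone (camera adjusted p = 0.859). Of imprinted genes 3 of 13 were lower, also when adjusted over the list alone (camera adjusted p = 0.423), with Sfmbt2 at -1.85 (SE 0.43; 16 of 16) and Ube3a at -0.56 (SE 0.17; 13 of 16). In MII oocytes 2 of 27 DNA replication genes were lower, also when adjusted over the list alone (camera adjusted p = 0.326), Prim1 at -0.79 (SE 0.22; 16 of 16) and Mcm3 at -0.93 (SE 0.26; 15 of 16). In 4-cell embryos 3 of 20 pluripotency and lineage genes were lower and 1 higher, also when adjusted over the list alone (camera adjusted p = 0.477), with Id2 at -1.22 (SE 0.36; 13 of 16), Gata4 at -1.02 (SE 0.35; 15 of 16) and Sall4 at 0.63 (SE 0.20; 14 of 16).

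Markers of other cells were rare. Of the cumulus and granulosa markers 3, 4, 2 and 1 were measured by stage, and in 2-cell embryos Nr5a2 at -0.70 (SE 0.18; 15 of 16) and Kitl at -0.84 (SE 0.27; 14 of 16) were lower, also when adjusted over the list alone. Of sperm transcripts Odf2 was the 1 measured in MII oocytes, at -0.35 (SE 0.11; 15 of 16; edgeR adjusted p = 0.0361). Of blood, skin and stroma markers 3 were measured in MII oocytes and edgeR called 0, with 0 at an unadjusted p under 0.05, 0 by DESeq2 and 1 by limma-voom. Pecam1 there was at 0.39 (SE 0.20; 13 of 16; edgeR adjusted p = 0.208). Of sex-linked genes 6 were measured in 4-cell embryos and edgeR called 0, with 1 at an unadjusted p under 0.05 and 0 by DESeq2 and by limma-voom (camera adjusted p = 0.728). Eif2s3y there was at 0.22 (SE 0.63; edgeR adjusted p = 0.855).

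Of 127 libraries 113 were nearest to the mean profile of their own group and 124 to their own stage. Besides 8-cell knockout replicate 7, 4-cell knockout replicate 16 was nearest to 8-cell knockout (0.850, own group 0.847) and 8-cell knockout replicate 16 to 4-cell wildtype (0.843, own group 0.813). An exchange of these 2 libraries between the stages was not tested and stays open. Without replicate 16 of either genotype edgeR called 1168 genes in 4-cell and 831 in 8-cell embryos.

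For the genotype effects, 1 of 100 splits of the libraries, the real one, gave as many genes at each stage, which argues against a chance split of single oocytes and embryos: 919 in MII oocytes (highest other 2), 1506 in 2-cell embryos (9), 1229 in 4-cell embryos (1) and 835 in 8-cell embryos (139). No label names the mothers, so such splits do not exclude a difference between females or collections of embryos. The number of gene lists called by camera, adjusted here within each stage and not over the 85 tests as elsewhere, does not exclude chance. As many lists were called in 25 of 100 splits in MII oocytes (real 2, highest other 7), 18 in 2-cell embryos (5 and 6), 32 in 4-cell embryos (5 and 9) and 9 in 8-cell embryos (10 and 11). For the stage changes 1 of 100, the real one, gave as many genes in each case. In wildtype these were 5235 (highest other 1), 8008 (0) and 1816 (8), and in knockout 5041 (35), 8077 (4357) and 1056 (505), for the 3 steps in order.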
